A study of Arabidopsis thaliana with 4 samples.

How the data were processed

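Chromatin contacts were measured by in situ Hi-C in Arabidopsis thaliana Columbia-0, in endosperm (the nutritive seed tissue that grows beside the embryo) and in leaves of 4-week-old plants. In Hi-C, chromatin is crosslinked with formaldehyde, cut with a restriction enzyme and religated, so that a sequenced ligation product joins 2 stretches of DNA that lay close together. The labels give 2 replicates per tissue, 4 samples in all. They name tissue as the only factor.

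The authors deposited 4 matrices of balanced contact signal, 1 per tissue at 100 kb bins and 1 per tissue at 200 kb bins. The matrices are named for replicates 1 and 2 together, so each tissue is a single pooled measurement. Reads were processed with HiC-Pro 2.9.0 and Bowtie2 on TAIR10, per the submitters' processing notes. The restriction enzyme, the read filters and the settings of the balancing are not given in the sources used here. The deposited signal was balanced by iterative correction, as the matrix names state, and each bin's total lay between 29020.5 and 29022.8 in leaf and between 39632.0 and 39637.0 in endosperm. Balancing removes differences in coverage between bins, including real differences in copy number, and it makes every value depend on the whole matrix.

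Whole contact counts were recovered from the balanced values, since each balanced value is a count divided by 1 factor for each of its bins. All pairs of bins came out whole within a tolerance of 0.01, with the largest distance from a whole number at 0.00349 in leaf and 0.00331 in endosperm. Summing the recovered 100 kb counts gave the 200 kb counts, within the same tolerance on the log scale, for 99.8% of pairs in each tissue. The depth was 18557893 contacts in leaf and 25033672 in endosperm. The median count was 26456 contacts per bin in leaf and 36409.5 in endosperm, and 16 and 21 contacts per interchromosomal pair of bins.

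Bins were laid out along chromosomes 1 to 5, and in each tissue 23 of 1193 bins (1.93%) had no signal. Bins with values for fewer than 50% of the other bins in either tissue were left out of both, which left 1168 bins. Region classes followed gene cover from a gene table of assembly TAIR10.1, which was used for names and for the bin each gene falls in. The pericentromere was the run of bins around the lowest 1 Mb running mean of gene cover in which that mean stayed under 0.5 of the chromosome's median. The 5 outermost bins with signal at each end were called ends. The heterochromatic knob was taken at 1.6 to 2.3 Mb of chromosome 4. The rest were arms, giving 197 pericentromeric, 914 arm, 50 end and 7 knob bins.

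Contacts between chromosomes were class means divided by the mean of all interchromosomal pairs. Contacts within chromosomes were divided by the mean at the same distance on the same chromosome. The main diagonal was left out. The decay exponent was the slope of log10 contact on log10 distance from 0.5 to 5 Mb, as the median over arms with at least 30 used bins. Compartment scores were the first eigenvector of the correlation matrix of observed over expected contacts, turned to correlate positively with gene cover and scaled to an SD of 1 without being centred on 0. Compartment strength was the mean contact of like bins over that of unlike bins, using the top and bottom 20% by score. Hubs were arm bins with at least 5 partners, over 5 Mb away or on other chromosomes, among the top 0.1% of such pairs.

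With 1 pooled matrix per tissue no test across replicates and no replicate SD can be given, and no p-value is printed. Each value has a 95% counting interval, which is the value plus and minus 1.96 SDs of 100 seeded Poisson draws of the recovered counts with the deposited balancing factors kept. It covers counting error only, and duplicates or pooled replicates add spread that it does not hold. A difference is called here when its interval excludes 0. The number of chromosomes, arms or chromosome pairs that share the direction is given beside it as a description, since these are parts of the same matrix and not replicates. Scores were also computed on 10 random divisions of the counts into equal parts, and hub counts on 20 matrices drawn with no hubs.

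Named regions followed a rule fixed before the data were examined: up to 10 merged hub regions per tissue with the most partners, the 10 longest runs of at least 2 bins whose within-arm score changed sign, the 5 bins with the largest rise and the 5 with the largest fall in interchromosomal share, every pericentromere, end and knob, and every member of 5 gene lists. The lists held 53 genes, all of which matched the gene table: paternally expressed imprinted genes, maternally expressed imprinted genes, type I MADS-box and other endosperm regulators, seed storage genes and photosynthesis genes. A list's median over its arm bins was placed among 10000 random sets of arm bins matched on 5 groups of gene cover.

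The measures were tested on simulated data. Counts were recovered for 100% of pairs of a leaf-like matrix of 1168 bins. A planted log2 difference of 0.25 in pericentromere contacts between chromosomes was measured as 0.26, and one of 0.58 in end contacts as 0.58. A planted difference of 3.90 percentage points in intrachromosomal share was measured as 3.91. The matrices with planted differences were not balanced, so the effect of balancing on these measures was not checked by simulation. All 8 planted hubs were called together with 8 bins that were not planted, so hub counts were read against the chance draws.

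Alternatives fixed beforehand were the 200 kb matrices, no bin filter, leaving out each chromosome, other pericentromere, end and distance definitions, an expectation from bin totals, medians, other decompositions, other hub thresholds and unmatched random sets. Chosen after seeing the data were leaving out chromosomes 1 and 2 together, thinning endosperm to the leaf total, leaving out 13 bins of over 2 times the median count, counts without balancing, subtracting the interchromosomal mean, the best of 3 eigenvectors, and lists without 1 bin of chromosome 1. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.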

Results

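Hi-C contact maps of Arabidopsis endosperm and leaf were compared to ask how chromatin is arranged in each tissue. Each tissue was represented by 1 map pooled from 2 replicates, with 18557893 contacts in leaf and 25033672 in endosperm. There was no replicate spread to compare with, so differences are given as endosperm against leaf, with a 95% counting interval where one is printed. Interchromosomal contacts numbered 11034545 in leaf and 14617359 in endosperm.

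A larger share of contacts lay within chromosomes, and a smaller share between them, in endosperm than in leaf. The maps do not tell copies of a chromosome apart, so contacts between copies count as intrachromosomal. The intrachromosomal share of contacts was 31.4% in leaf and 34.6% in endosperm, a difference of 3.24 percentage points (3.20 to 3.28). It was higher in endosperm on 5 of 5 chromosomes, by 4.22 and 3.93 points on chromosomes 1 and 2 and by 2.53 to 2.77 points on the others. The leaf map joins segments of chromosomes 1 and 2, and contacts between the joined segments count as interchromosomal. With contacts inside each 100 kb bin counted too, the difference over all chromosomes was 1.21 points. Random ligation between nuclei or another difference in library preparation could also shift this share, and neither was tested for it.

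Among contacts between different 100 kb bins of a chromosome, those of endosperm were shifted toward short distances. Contacts inside a bin, the shortest, were left out here. They numbered 3087534 in leaf, beside 4435814 between bins of a chromosome, and 3533125 beside 6883188 in endosperm, a smaller part. The shift therefore does not cover distances inside a bin. Contacts over more than 2 Mb made up 64.1% of intrachromosomal contacts in leaf and 59.3% in endosperm, a difference of -4.80 points (-4.87 to -4.74), and the share was lower on 5 of 5 chromosomes. Contact fell with distance with an exponent of -0.286 in leaf and -0.429 in endosperm, a difference of -0.144 (-0.150 to -0.138). The decay was steeper in endosperm in 8 of 8 arms, most on the south arm of chromosome 2 (-0.279 against -0.442) and least on the south arm of chromosome 1 (-0.426 against -0.444), which is broken at 22.7 Mb in the leaf map and has the steepest leaf decay. Among the other arms the least change was on the north arm of chromosome 3 (-0.363 against -0.432). At 0.5 Mb, contact within arms was 3.59 times the interchromosomal mean in leaf and 5.56 times in endosperm, and at 5 Mb it was 1.66 and 1.85 times. The size of the exponent difference depended on the distances fitted: it was -0.05 over 1 to 10 Mb and -0.23 over 0.3 to 2 Mb.

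**Figure D1:**
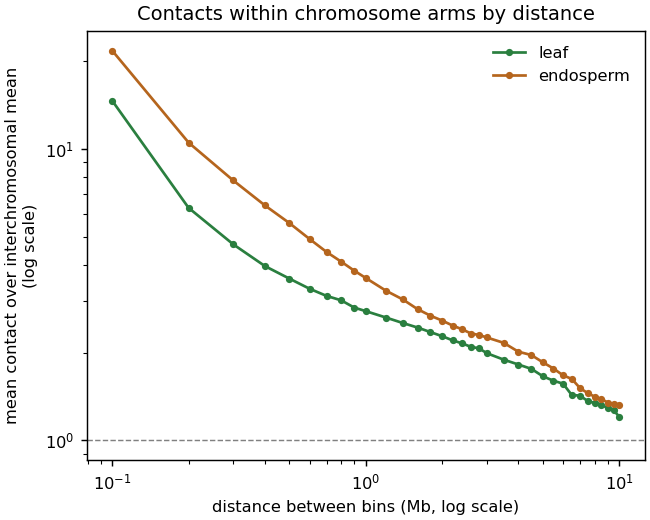
Mean contact within chromosome arms (log scale, over the interchromosomal mean) against the distance between bins in Mb (log scale), in leaf and endosperm, with points at the distances measured. The endosperm line lies above the leaf line, 21.7 against 14.6 at 0.1 Mb, and the lines approach each other with distance, 1.32 against 1.21 at 10 Mb.

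Pericentromeres, the gene-poor and repeat-rich regions beside the centromeres, contacted the pericentromeres of other chromosomes more in endosperm. Their mean contact was 0.965 of the interchromosomal mean in leaf and 1.10 in endosperm, a log2 difference of 0.19 (0.18 to 0.20), and it was higher in 10 of 10 chromosome pairs. Contacts of pericentromeres with the arms of other chromosomes rose from 0.926 to 0.981, a log2 difference of 0.08 (0.08 to 0.09), in 19 of 20 combinations. Arm to arm contacts between chromosomes went the other way, from 1.03 to 0.997, a log2 difference of -0.04 (-0.04 to -0.04), and were lower in 10 of 10 pairs. The largest fall was between chromosomes 1 and 2 (log2 -0.15, against -0.042 to -0.007 in the other pairs), which the leaf map joins. The combination of pericentromere and arm that fell was also of these, chromosome 2 with the arms of chromosome 1 (1.05 to 0.973). Inside each pericentromere, contact over that expected from distance was lower in endosperm on 5 of 5 chromosomes, ranging from 1.08 to 1.32 in leaf and from 0.907 to 1.01 in endosperm. The pericentromere difference rested on the reference chosen: with an expectation from both bins' interchromosomal totals the values were 1.10 and 1.09 (log2 -0.01), and the log2 differences of pericentromere to arm and arm to arm contacts were 0.0017 and -0.0015. In counts without balancing, where a few repeat bins dominate, they were 3.58 and 2.82 (log2 -0.34), and without those bins 0.733 and 0.872 (log2 0.25).

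**Figure D2:**
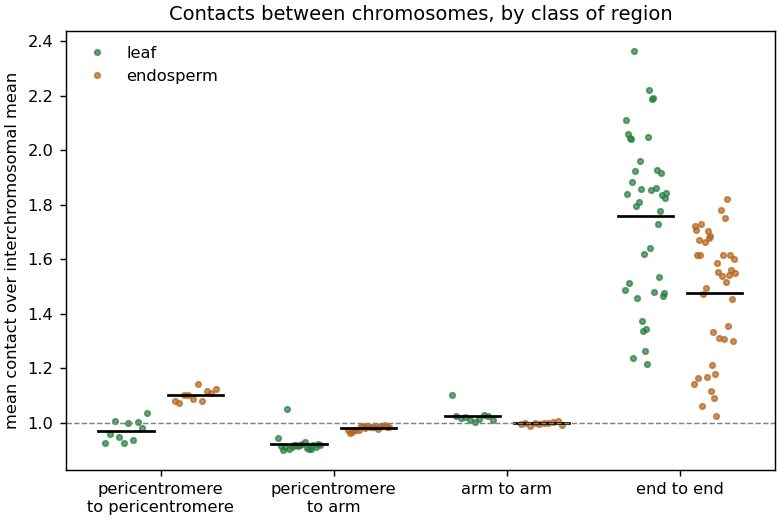
Mean contact between chromosomes over the interchromosomal mean, for 4 classes of region in leaf and endosperm. Each point is 1 pair of chromosomes or chromosome ends, and black bars are means over the points. All 10 pericentromere pairs are higher in endosperm, and 39 of 40 end pairs are lower.

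Within chromosomes, contacts of pericentromeres with their own arms did not differ detectably at this depth, at 0.930 of the distance expectation in leaf and 0.929 in endosperm (log2 0.00, interval -0.01 to 0.00). Opposite arms of a chromosome contacted each other at 1.02 times the distance expectation in leaf and 1.01 in endosperm. The log2 difference was -0.01 (-0.01 to -0.01), with 2 chromosomes higher and 3 lower in endosperm, so this difference was not shared by the chromosomes. It was 0.19 on chromosome 2, which is broken in the leaf map at 1.5 Mb, and -0.03 to 0.004 on the others.

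The interchromosomal share per bin separated pericentromeres from arms in opposite ways in the tissues. In leaf, pericentromeric bins had a lower interchromosomal share than arm bins (66.0% against 68.9%), and in endosperm a higher one (66.3% against 64.9%). The contrast of pericentromere minus arm was -2.83 points in leaf and 1.41 points in endosperm, a difference of 4.25 points (4.17 to 4.32), in the same direction on 5 of 5 chromosomes. These values pool chromosomes of different shares: within single chromosomes the contrast was -4.38 to -2.89 points in leaf and 0.237 to 1.34 points in endosperm. Without repeat bins the pooled contrast was -3.32 points in leaf and 0.919 points in endosperm. Arms changed by -3.94 points (-3.98 to -3.90) and chromosome ends by -4.46 points (-4.56 to -4.36), from 74.4% to 69.9%, while pericentromeres differed by 0.307 points (0.230 to 0.384). The share was lower in endosperm in 908 of 914 arm bins and in 50 of 50 end bins. It was higher in 131 of 197 pericentromeric bins.

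The 5 largest rises in interchromosomal share were all pericentromeric. They lay at 14.2 to 14.3 Mb of chromosome 3 (73.8% to 78.3%, in a bin whose raw count also rose from 3.37 to 6.72 times the median), 11.4 to 11.5 Mb and 13.1 to 13.2 Mb of chromosome 5, 13.2 to 13.3 Mb of chromosome 1 and 4.9 to 5.0 Mb of chromosome 4. The last 4 rose by 2.26 to 2.71 points. The 5 largest falls were at 0.2 to 0.3 Mb (81.1% to 71.8%) and 1.0 to 1.1 Mb of chromosome 2 and at 22.8 to 22.9, 24.0 to 24.1 and 24.8 to 24.9 Mb of chromosome 1. These lie on segments of chromosomes 1 and 2 that the leaf map joins at 22.7 and 1.5 Mb. Leaf contact between the joined sides was 3.40 to 3.59 times the interchromosomal mean. The knob on the short arm of chromosome 4, a block of heterochromatin, did not differ detectably in share (69.6% and 69.4%, difference -0.20, interval -0.51 to 0.11). Its contact with the pericentromeres of other chromosomes was 0.918 in leaf and 1.08 in endosperm (log2 0.24).

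**Figure D3:**
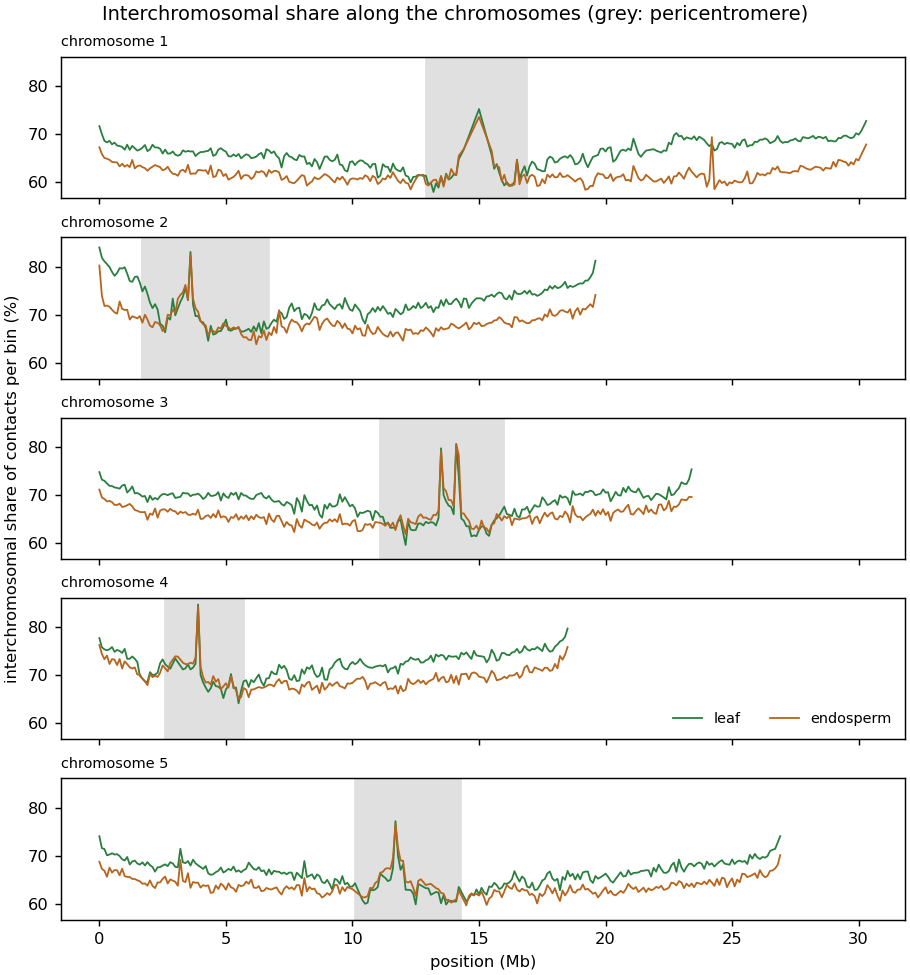
Interchromosomal share of contacts per 100 kb bin (%) along chromosomes 1 to 5 (position in Mb) in leaf and endosperm, with pericentromeres in grey. Arms lie lower in endosperm, with a mean difference of -3.94 points, while the pericentromeric lines overlap.

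Chromosome ends contacted each other more than average in both tissues, and less so in endosperm. Mean contact between ends of different chromosomes was 1.76 in leaf and 1.48 in endosperm, a log2 difference of -0.25 (-0.28 to -0.23), lower in 39 of 40 pairs. The exception was the north end of chromosome 3 with the south end of chromosome 5 (1.73 and 1.82). The largest fall, log2 -0.68, was between the south ends of chromosomes 1 and 2 (2.36 and 1.47), which lie on segments that the leaf map joins. The north ends of chromosomes 2 and 4 carry the nucleolus organizers, the arrays of ribosomal RNA genes. The 25 pairs without such an end went from 1.96 to 1.63 (log2 -0.26, -0.29 to -0.24), the 14 pairs with 1 such end from 1.42 to 1.21 (log2 -0.23, -0.28 to -0.19), and the pair of both from 1.62 to 1.33 (log2 -0.28, -0.42 to -0.14). Ends of 1 Mb gave a log2 difference of -0.11, and counts without balancing gave -0.05.

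Compartments, the division of a chromosome into regions that prefer contacts with their own kind, were weaker in endosperm along each tissue's own score. Compartment strength was 1.47 in leaf and 1.22 in endosperm, a log2 difference of -0.27 (-0.32 to -0.22), lower on 5 of 5 chromosomes. It was -0.57 with the top and bottom 10% of bins and -0.04 with 50%. By chromosome the log2 difference was -0.36 and -0.39 on chromosomes 1 and 2, which are broken in the leaf map. On chromosomes 3, 4 and 5 it was -0.09, -0.37 and -0.13. Whole-chromosome scores of the tissues correlated across 1168 bins with r = 0.32 (0.16 to 0.49), from 0.00973 on chromosome 1 to 0.844 on chromosome 4. The r was also low on chromosomes 3 and 5 (0.12 and 0.08), which the junction does not break. Within arms r was 0.34 (0.28 to 0.40) across 928 bins, and 0.59 from the log2 matrix without the correlation step. Bins are not independent replicates. Random divisions of the counts correlated at 0.959 in leaf but 0.550 in endosperm for whole-chromosome scores, and at 0.820 and 0.625 within arms, so the endosperm scores were less repeatable although its map was deeper. The whole-chromosome endosperm score followed position along chromosomes 1, 3 and 5 with r of -0.49, -0.50 and -0.52 (leaf 0.36, -0.02 and 0.15). On these chromosomes its r with gene cover was 0.14, 0.11 and 0.22, against 0.12, 0.56 and 0.55 in leaf. On chromosomes 2 and 4 it was 0.38 and 0.64, against 0.34 and 0.63 in leaf. On chromosomes 3 and 5 the strengths of the tissues therefore rest on unlike scores. Within arms it was the leaf score that followed position more closely in 7 of 8 arms, with r from -0.73 to 0.73 in leaf and from -0.53 to 0.52 in endosperm, which bears on the sign changes below.

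Within-arm scores had opposite signs in 48.1% of bins, and in 36.0% once each tissue's scores were centred on the median of each arm, since the mean score was -0.73 in leaf and 0.34 in endosperm. From the log2 matrix the value was 30.4%, and with the best of 3 eigenvectors 34.6%. Of 84 runs of sign change, the longest covered 18 bins at 4.3 to 6.1 Mb of chromosome 3, with mean scores of -0.78 in leaf and 0.99 in endosperm. Others that were higher in endosperm lay at 13.4 to 15, 15.3 to 16.4 and 16.5 to 18.0 Mb of chromosome 2, at 23.1 to 24.5 Mb of chromosome 5, at 17.7 to 18.4 and 21.2 to 22.2 Mb of chromosome 3 and at 18.1 to 18.8 Mb of chromosome 1. The runs at 24.3 to 25.2 and 25.4 to 26.1 Mb of chromosome 1 were lower in endosperm (1.18 against -1.96, and 0.93 against -0.96), on an arm that is broken in the leaf map at 22.7 Mb. The difference in mean score carries into these runs: of the 114 bins in the 10 longest, 61 still had opposite signs after centring. Of all runs 77 were higher and 7 lower in endosperm before centring, and 38 and 25 after. The longest run of centred scores, a measure added after the data were seen, was at 0.2 to 2.1 Mb of chromosome 1 and lower in endosperm (0.64 against -0.93).

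Long-range contact hubs were called at 46 bins in leaf and 2 in endosperm, with 0 shared. Of the leaf hub bins, 45 were on chromosomes 1 and 2, and 349 of the 383 strongest leaf pairs lay between these chromosomes. The leaf map joins them at 22.7 Mb of chromosome 1 and 1.5 Mb of chromosome 2. Contact between the joined sides was 3.40 to 3.59 times the interchromosomal mean. The contrast of 46 with 2 therefore cannot be separated from this junction. The leading leaf regions were at 0.5 to 1.7 Mb of chromosome 2 with 81 partners, and at 21.9 to 22.8 Mb of chromosome 1 with 12. They were followed by chromosome 1 regions at 19.4 to 19.8, 20.3 to 21.2, 21.3 to 21.7, 18.8 to 19.1, 20.1 to 20.2, 16.9 to 17.0 and 17.1 to 17.2 Mb, with 5 to 10 partners each. The leaf hub off these chromosomes was at 22.5 to 22.6 Mb of chromosome 3 with 6 partners. The endosperm hubs were at 24.2 to 24.3 Mb of chromosome 1 with 12 partners and at 5.8 to 5.9 Mb of chromosome 4 with 9. Chance draws gave a mean of 4.9 hubs in leaf (highest 8) and 6.9 in endosperm (highest 10), so the endosperm count was not above chance. Without chromosomes 1 and 2, 5 leaf hubs and 0 endosperm hubs were called (chance means 0.25 and 0.95), and with the top 0.5% of pairs the order turned, with 269 in leaf and 371 in endosperm.

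**Figure D4:**
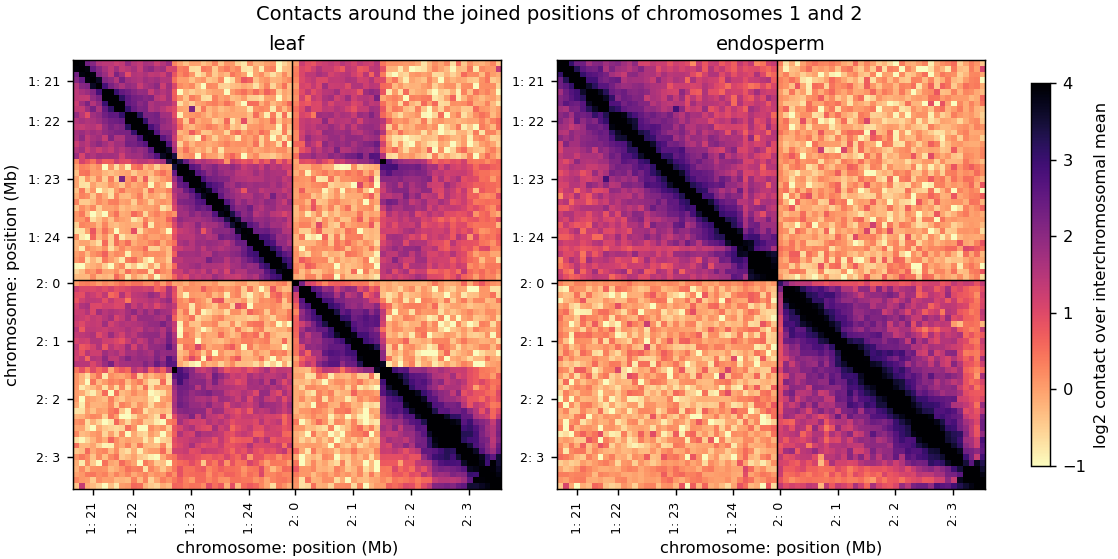
Contact maps of leaf and endosperm around the positions of chromosomes 1 and 2 that the leaf map joins (axes: chromosome and position in Mb, colour: log2 of contact over the interchromosomal mean). In leaf the bin pair at the crossing holds 321 contacts and the neighbour contacts break at 22.7 Mb of chromosome 1 and 1.5 Mb of chromosome 2, while in endosperm the same pair holds 21.

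**Figure D5:**
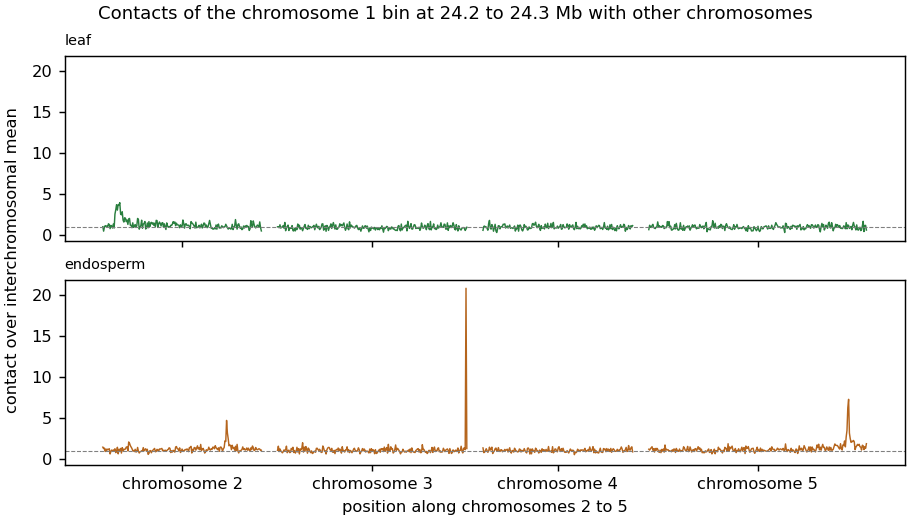
Contact of the chromosome 1 bin at 24.2 to 24.3 Mb with each bin of chromosomes 2 to 5, over the interchromosomal mean, in leaf and endosperm. Endosperm has peaks of 20.8 on chromosome 3, 7.26 on chromosome 5 and 4.70 on chromosome 2, where leaf reaches at most 1.18.

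The bins of the fixed gene lists were compared to ask whether genes active in 1 of the tissues lie in bins that moved more than others. The bins of paternally expressed imprinted genes, which include PHE1, HDG3 and YUC10, changed their interchromosomal share by a median of -3.11 points, with 1 bin higher and 8 lower, at percentile 94.7 of random sets. Those of maternally expressed imprinted genes such as MEA and FIS2, members of the Polycomb complex of the seed, changed by -3.67 points (5 of 5 lower, percentile 57.8). Type I MADS-box and other endosperm regulators, among them AGL62 and IKU2, changed by -3.98 points (1 higher and 7 lower, percentile 40.5). Seed storage genes, the cruciferins, albumins and oleosins, changed by -3.94 points (6 of 6 lower, percentile 55.5), and photosynthesis genes by -3.87 points (14 of 14 lower, percentile 46.6). None of the 5 lists lay outside the central 95% of random sets.

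In within-arm score, the median change was 0.93 for paternally expressed genes (percentile 29.3), 1.13 for maternally expressed genes (51.4), 1.97 for the MADS-box and regulator list (96.1), 1.25 for seed storage (61.8) and 1.10 for photosynthesis (46.7). Again 0 of 5 lists lay outside the central 95% of random sets, whose own medians were near 1.1 because the scores are not centred. In the regulator list, AGL80 (-1.72 in leaf, 1.15 in endosperm), ZOU (-0.93 and 1.66) and AGL62 (-1.62 and 0.72) had higher scores in endosperm, while AGL40 did not (0.15 and -0.26). ZOU and MINI3 of this list lie on the south arm of chromosome 1, which is broken at 22.7 Mb in the leaf map. The leaf score of that arm followed position (r = 0.73) more than gene cover (r = 0.18). The random sets were matched on gene cover and not on arm. PHE1, PHE2 and AGL23 share the bin at 24.2 to 24.3 Mb of chromosome 1, which holds extra counts in endosperm (2.06 times the median against 1.07 in leaf). Without this bin the regulator list's score change was at percentile 98.5, and the share change of paternally expressed genes was -3.56 points at percentile 76.5. Over all alternatives, no list median lay outside the central 95% in 7 of 12.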

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

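The tests of random ligation, of leaving out chromosomes 1 and 2, of counts without balancing and of the chromosome 1 bin at 24.2 Mb were chosen after the results were seen, as were the limits used to pick bins by raw count; the test of collapsed repeats was fixed before its result.

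Pericentromeres and arms changed places in interchromosomal share, which is a difference between the tissues that points one way in all 5 chromosomes of leaf and the other way in all 5 of endosperm. Pericentromere minus arm was -2.83 points in leaf and 1.41 points in endosperm, a difference of 4.25 points. Within single chromosomes the contrast was -4.38 to -2.89 points in leaf and 0.237 to 1.34 points in endosperm, and the pooled endosperm value fell to 0.919 points without repeat bins. With 1 pooled map per tissue this difference was not tested across replicates.

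The same pattern appeared as more contact between pericentromeres of different chromosomes in endosperm (log2 0.19). In balanced maps, reads of collapsed repeats are not the whole source, since without bins of over 2 times the median count the log2 difference was 0.21. The junction of chromosomes 1 and 2 in the leaf map is not either, since the log2 difference was 0.14 without those chromosomes. Random ligation between nuclei alone would draw a leaf value under 1 toward 1 and not past it, while the balanced endosperm value was 1.10; it may still contribute, since in counts without balancing and repeat bins the values were 0.733 and 0.872 (log2 0.25, or -0.34 with repeat bins). The result also rests on the reference: with expectations from bin totals the log2 difference was -0.01, so once each bin's amount of interchromosomal contact was allowed for, no excess between pericentromeres was left in endosperm over leaf. A difference between the tissues stays open as untested, and so does any difference in library preparation, which the pooled maps cannot separate from tissue.

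Raw counts per bin, which the balanced comparisons do not use, differed at a few bins far beyond the rest, whose log2 ratio of endosperm over leaf lay between -0.11 and 0.17 from the 1st to the 99th percentile. Lower in endosperm were the bins from 3.6 Mb of chromosome 2 (-0.55), 15 Mb of chromosome 1 (-0.50), 3.9 Mb of chromosome 4 (-0.47), 11.7 Mb of chromosome 5 (-0.43) and 13.5 Mb of chromosome 3 (-0.42), all pericentromeric and at 3.82 to 36.6 times the median count. A sixth bin under -0.3, from 13.7 Mb of chromosome 3 (-0.37), was also pericentromeric but had a low count, 0.788 of the median in leaf and 0.609 in endosperm. Higher in endosperm were the bins from 3.4 Mb (1.19), 3.3 Mb (0.88) and 3.2 Mb (0.73) of chromosome 2, and from 14.2 Mb (1.00) and 14.1 Mb (0.91) of chromosome 3. The first bin of chromosome 2, which like the last of these holds 2 ribosomal RNA genes of the gene table, was also higher (0.72).

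The bin at 24.2 to 24.3 Mb of chromosome 1, which holds PHE1, PHE2 and AGL23, was the arm bin that stood out in raw count (log2 0.94, against at most 0.21 in any other arm bin). In endosperm it contacted chromosome 3 at 23.3 to 23.4 Mb 20.8 times above the interchromosomal mean (1012 contacts against 15 in leaf), chromosome 5 at 24.7 to 24.8 Mb 7.26 times (332 against 22) and chromosome 2 at 15.3 to 15.4 Mb 4.70 times (203 against 20). A repeat shared by these sites in the reference would show in leaf, where the highest value was 1.18, and a contact of the locus in place would extend to the bins beside it, whose mean was 1.39 although 1 pair reached 3.24. Extra copies of sequence from this bin at other sites stay open. They predict a raised count, but this count is what flagged the bin and so does not test them. The bin also held 3 of the 4 bin pairs with high contact in endosperm only. Its contacts tapered along chromosome 5 (6.23 and 3.15 beside 7.26) and chromosome 2 (2.14 and 3.18 beside 4.70). On chromosome 3 the peak was confined to 1 bin (1.14 and 1.28 beside 20.8), and what sets it apart was not tested. One hypothesis is a transgene: the chromosome 3 bin holds RANGAP1, a gene singled out after the values were seen and known as a source of nuclear envelope tags, but the labels call both tissues wild type and name no construct, and no genome sequence was used here to test it.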

How the results depend on the processing

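The settings that leave out chromosomes 1 and 2 together, thin endosperm, leave out repeat bins, use counts without balancing, subtract the interchromosomal mean, use the best of 3 eigenvectors or leave out 1 bin of the gene lists were chosen after the data were seen. Of 232 values of 16 results under alternatives, 99 stayed within the counting interval (or within 1.5 times, for counts), 131 moved outside it and 2 turned direction, counting only differences between the tissues whose interval excluded 0. Outside that count, pericentromere to arm contacts within chromosomes changed sign in 4 of 13 alternatives. The order of the hub counts turned at the top 0.5% of pairs, a cut for which no chance count is given. Of 120 values of single gene lists, 107 stayed, 13 moved and 0 turned. No paired analysis was possible because both replicates of a tissue are pooled in 1 matrix. Except where fewer bins or pairs enter by construction, the cause was not tested. Thinning endosperm to the leaf total left both score correlations within their intervals (0.36 and 0.32). At this depth pericentromere to arm contacts within chromosomes could not be told apart between the tissues, and the endosperm hub count was not above chance draws.

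As log2 of endosperm over leaf, pericentromere contacts between chromosomes turned to -0.014 with expectations from bin totals and to -0.34 in counts without balancing (0.25 there without repeat bins). They were 0.16 in 200 kb bins, 0.18 with pericentromeres of 2 Mb each side, 0.23 by medians, 0.14 without chromosomes 1 and 2 and 0.21 without repeat bins. Leaving out each chromosome gave 0.16 to 0.21.

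Pericentromere to arm contacts between chromosomes were 0.0017 with bin totals, 0.062 and 0.088 with the wider and the 2 Mb pericentromere, 0.080 by medians, 0.089 without chromosomes 1 and 2, 0.16 without balancing and 0.098 there without repeat bins (leave-one-out 0.078 to 0.094). Arm to arm contacts were -0.0015 with bin totals, -0.054 by medians, -0.045 without chromosomes 1 and 2, -0.041 without repeat bins, -0.056 without balancing and -0.045 there without repeat bins (leave-one-out -0.050 to -0.039). Chromosome ends gave -0.23 in 200 kb bins, -0.21 with bin totals, -0.19 by medians, -0.37 with ends of 0.3 Mb, -0.11 with ends of 1 Mb, -0.19 without chromosomes 1 and 2, -0.045 without balancing and -0.19 there without repeat bins (leave-one-out -0.28 to -0.21).

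Within chromosomes, pericentromere to arm contacts were -0.027 and 0.011 with the wider and the 2 Mb pericentromere and 0.015 without chromosomes 1 and 2 (leave-one-out -0.0093 to 0.0049); the interval of this difference included 0, and 9 of 13 alternatives shared its sign. Opposite arms gave -0.014 without chromosomes 1 and 2 (leave-one-out -0.019 to -0.0011).

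The intrachromosomal share difference was 3.02 points in 200 kb bins, 1.21 with the diagonal, 2.87 without the first off-diagonal, 2.98 without chromosomes 1 and 2, 3.33 without repeat bins, 3.35 without balancing and 3.45 there without repeat bins (leave-one-out 2.96 to 3.90). The long-range share gave -4.60 in 200 kb bins, -4.42 without the first off-diagonal, -4.06 over 5 Mb, -4.94 without repeat bins and -5.25 there without balancing (leave-one-out -5.09 to -4.56). The decay exponent difference was -0.135 in 200 kb bins, -0.0490 over 1 to 10 Mb, -0.230 over 0.3 to 2 Mb, -0.114 over all pairs and -0.165 with the interchromosomal mean subtracted (leave-one-out -0.147 to -0.123). The regional share contrast was 3.80 in 200 kb bins, 4.34 without the bin filter, 4.73 without chromosomes 1 and 2, 3.75 without balancing and 4.15 there without repeat bins (leave-one-out 4.49 to 4.77).

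Compartment strength (log2) was -0.33 in 200 kb bins, -0.21 from the log2 matrix, -0.57 with 10% of bins, -0.036 with 50% of bins, -0.20 without chromosomes 1 and 2, -0.20 without repeat bins and -0.40 with the best of 3 eigenvectors. The within-arm score correlation was 0.27 in 200 kb bins, 0.26 with the wider pericentromere, 0.59 from the log2 matrix, 0.52 without chromosomes 1 and 2 and 0.42 with the best of 3 eigenvectors (leave-one-out 0.24 to 0.48). The whole-chromosome score correlation stayed within its interval in 14 of 14.

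Leaf hubs numbered 15 in 200 kb bins, 24 at the top 0.05% and 269 at the top 0.5% of pairs, 20 with at least 10 partners and 5 without chromosomes 1 and 2 (leave-one-out 6 to 33). Endosperm hubs numbered 1 in 200 kb bins, with either other pericentromere, at the top 0.05%, with at least 10 partners and without repeat bins, 5 with bin totals and after thinning, 371 at the top 0.5%, 58 with at least 3 partners and 0 without chromosomes 1 and 2 (leave-one-out 1 to 2). The number of list medians outside the central 95% of random sets went from 0 to 1, always the score of the endosperm regulators, without repeat bins and without the chromosome 1 bin with extra counts (leave-one-out 0 to 1).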

Other observations

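All tests in this part were chosen after the result was seen.

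Away from chromosomes 1 and 2, 5 arm bins of leaf were called as hubs: 1.9 to 2.0 and 22.5 to 22.6 Mb of chromosome 3, 15.5 to 15.6 Mb of chromosome 4, and 4.7 to 4.8 and 4.8 to 4.9 Mb of chromosome 5. Each had 6 or 7 partners. Draws with no hubs over the same 3 chromosomes gave a mean of 0.25 and at most 1 such bin; they hold counting noise only. Their contacts over expected were 2.31 to 3.24 in leaf and 1.46 to 1.71 at the same pairs in endosperm, although pairs picked in leaf are biased upward there. The pair of bins at 16.8 to 16.9 Mb of chromosome 1 and 12.1 to 12.2 Mb of chromosome 5 had 86 contacts in endosperm (5.24 times the interchromosomal mean) and 9 in leaf.

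The leaf map joins chromosome 1 at 22.7 to 22.8 Mb with chromosome 2 at 1.5 to 1.6 Mb. Contact across these positions was 1.65 and 1.83 times the interchromosomal mean in leaf and 6.35 and 8.46 in endosperm. The positions were picked as those with the lowest leaf to endosperm ratios of 1022 positions, on different chromosomes (log2 -1.94 and -2.20). Their rank is therefore the rule of choice and not a result. With positions within 10 bins of either left out, the lowest was -0.95. The bin pair at the crossing, picked as the one with the highest leaf contact near both positions, had 321 contacts in leaf and 21 in endosperm.

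A repeat shared by the sites would raise the same block in endosperm, where it was 0.909 of the interchromosomal mean. A contact between intact chromosomes would leave neighbours across the chromosome 1 position in contact. They kept -0.11% of the excess that neighbours have over the mean. The position was picked for low leaf contact across it, so this value is not an independent test. A reciprocal exchange carried by the leaf plants is a candidate explanation, since the new neighbours reached at least 126% of that excess while the raw counts of the exchanged segments stayed level (log2 -0.01 and -0.01). The labels call the leaf plants wild type, and whether they came from a line with such an exchange, for example one carrying an insertion, was not tested. A difference between the tissues in the folding of intact chromosomes would keep neighbours in contact across both positions. In leaf they kept -0.11% of the excess across the chromosome 1 position and -4.76% across the chromosome 2 position. Both positions were picked for low contact across them in leaf relative to endosperm, so these values do not decide about such a folding difference.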
